A study of Mus musculus with 84 samples.

How the data were processed

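The samples were 84 single neurons of mouse (strain C57/BL6/N) prefrontal cortex slices, patch-clamped, with RNA amplified by the aRNA procedure and made into libraries with a stranded Illumina TruSeq kit, per the labels' protocols. Groups came from the titles, as 25 F and 59 P cells, and the basecaller version from the labels, with 3 F and 6 P cells under 1.8.4 and 22 F and 53 P cells under 2.17. They are called the older and the newer batch after the bcl2fastq version alone, not a recorded date or run. The deposited table holds raw counts of reads per gene symbol, whole numbers that sum to different totals per cell, for 19685 genes. Reads were aligned with STAR 2.4.0 to mm10 after bcl2fastq 1.8.4 or 2.17, per the submitters' processing notes. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies could be split in ways that cannot be checked. The table has no gene with 0 counts in all cells, and it lists no mitochondrially encoded gene. The ribosomal RNA gene Rn45s held up to 78.5% of a cell's counts.

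Counts were divided by the cell total and multiplied by 1000000 to give CPM, and CPM was averaged over the cells of a group with equal weight. The fold is (mean F + 1)/(mean P + 1), and a log2 fold above 0 is higher in F cells. Beside it were computed the percent of pairs of an F and a P cell with the F cell higher (ties shared equally), the percent of cells with at least 1 count with exact Clopper-Pearson 95% intervals, summed counts with exact Poisson intervals, and the ratio of pooled counts with an exact conditional interval. Cells were also thinned without replacement to 86539 counts, the 10th percentile of the totals, which left out 3 F and 6 P cells. A gene was measured if it had a count in at least 8 cells, which 11324 had. For a gene at 0 in a group, the ratio of pooled counts, not the fold of mean CPM, was bounded with a floor of 3 counts over the group. Setting such members at their bound moved no list median.

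Because the labels name no animal, each group is 1 sample, and no test, p-value, standard error or count of changed genes was made. For each of 28 gene lists, the share of measured members with a higher mean in F was given with an exact binomial interval over members, and the percentile of their median log2 fold among 10000 random lists of the same size matched on mean expression, as a description of these cells. Members of a list are not independent, so the interval is a guide only. Named genes followed a rule fixed before the data were examined: the first 12 in each direction by share of pairs, among genes found after thinning in at least 40% of the cells of a group, with a fold of at least 2 and the same direction in both basecaller versions; up to 2 members of each list in each direction with a fold of at least 2, or up to 3 for lists of surface proteins; and 11 markers whatever their values. Predicted genes, Rik clones and mitochondrial genes were not ranked. The rule gave 152 genes, of which 141 are named in the report. The other 11 are not reported here, keep their ranks and were not replaced. Members of 4 lists that match the list pattern by name only are named with those lists. They, and genes first named in the closing part, were chosen after their values were seen.

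Cell totals set the precision. The shallowest F cell had 36594 counts and the shallowest P cell 19802. Poisson and pooled-ratio intervals and floors cover counting error only, detection intervals the draw of cells, and list intervals the draw of members. Libraries F11 and F12 had the highest correlation of any pair, but their counts differed by more than sampling noise and both were kept. Alternatives fixed before the data were examined were pooled counts, means trimmed by 20% at each end, the difference of mean log2(CPM + 1), TMMwsp factors from edgeR, totals without the 20 genes with the highest counts, a pseudocount of 10 CPM, no low-count filter or a minimum of 21 cells, thinning, a detection limit of 5 counts, and each basecaller version alone. Further alternatives were chosen after the data were seen: without the 16 F libraries with shared reads, with F11 and F12 averaged, with totals without Rn45s, without libraries under 100000 counts, without P67, and lists without members caught by name only.

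The fold was tested on simulated gamma-Poisson counts drawn from the real means and totals, with 200 of the 11324 measured genes changed, all with a mean of at least 50 CPM. After the median fold of all measured genes was subtracted, the median estimate was -1.98 for a simulated log2 change of -2, -1.10 for -1, 1.07 for 1 and 2.03 for 2, over 50 genes each. The reported folds had no such median subtracted, and their median over measured genes was -0.79. The simulation therefore tested centred folds only. That simulation used a dispersion of 1 and treats cells as draws from 1 profile, so it does not cover the spread of these cells. Gene coordinates are from GENCODE M21 on GRCm38, the assembly of mm10, matched by symbol, with 1 of the 141 genes unmatched. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.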

Results

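The data were messenger RNA counts from 84 single neurons of mouse prefrontal cortex. Each neuron was collected through a patch-clamp pipette from an acute slice. Its RNA was amplified by the aRNA procedure, which copies polyadenylated RNA through in vitro transcription. The titles carry the letter F for 25 neurons and the letter P for 59. The series title names pyramidal and fast-spiking cells, whose initials match these letters. No label spells the letters out, so the groups are called F cells and P cells. Pyramidal cells are the glutamatergic projection neurons of cortex, and fast-spiking cells are GABAergic interneurons. No label names an animal, so each group counted as 1 sample and no p-value was computed. Every interval is a 95% interval, over cells for shares of cells, over members for gene lists, and over counts for pooled ratios. Those of pooled ratios, and floors, cover counting error only, because amplified reads without molecular identifiers are not independent molecules, and none covers differences between animals.

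Depth differed between the groups and between batches. Totals ran from 36594 to 12043599 counts in F cells, with a median of 680044, and from 19802 to 16251918 in P cells, with a median of 2706396. The median number of genes with at least 1 count was 2195 in F cells (quartiles 1811 and 3710) and 3488 in P cells (quartiles 2109 and 4633.5). After every cell was thinned to 86539 counts, 22 F and 53 P cells remained, with medians of 1092.5 and 1587 genes. The libraries are called an older and a newer batch by bcl2fastq version alone, not by a recorded date or run. In the older batch the median total was higher in F cells, at 5535888 against 3399452.5 counts, and in the newer batch higher in P cells, at 2377886 against 370712.5. In the older batch the medians were 4978 genes in 3 F cells and 5857 in 6 P cells. In the newer batch they were 1995.5 in 22 F cells and 3446 in 53 P cells. Shares of cells with a count of a gene are given at these unequal depths, before thinning. Levels are mean counts per 1000000 (CPM). Of 11324 genes with a count in at least 8 cells, 34.7% were higher in F cells, and the median log2 fold of F over P was -0.79. The share was 35.4% in the older and 32.7% in the newer batch, 34.4% after thinning and 18.7% with trimmed means. Each gene list is set beside these shares, and its median beside 10000 random lists matched on expression.

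Genes of GABAergic neurons were higher in F cells and genes of glutamatergic neurons higher in P cells. Gad1, a glutamate decarboxylase that makes GABA, averaged 1460.3 CPM in F cells and 128 CPM in P cells. It was found in 72% (95% interval 50.6 to 87.9%) against 45.8% (32.7 to 59.2%) of cells. Slc17a7, the vesicular glutamate transporter of cortical projection neurons, averaged 12.8 CPM in F cells and 202 CPM in P cells. It was found in 44% (95% interval 24.4 to 65.1%) against 67.8% (54.4 to 79.4%) of cells. Gad2, the other glutamate decarboxylase, was found in 16 of 25 F cells and 25 of 59 P cells. In 16 F libraries that share reads, described with the leading genes, Gad2 averaged 7.81 CPM, under the 103 CPM of P cells. It averaged 1221 CPM in the other 9 F libraries. Gad1 averaged 864 CPM in the 16 and 2520 CPM in the other 9, both above P cells. Slc17a7 averaged 19.6 and 0.75 CPM, both below P cells. Pvalb, a calcium-binding protein of many fast-spiking cells, was found in 2 of 25 F cells and 5 of 59 P cells (8% and 8.47%). These are fewer than the 8 cells required, so Pvalb is not among the measured markers, and its means give a log2 fold of 2.83. On mm10 the leading markers are Gad1 (ENSMUSG00000070880.10, chromosome 2, 70553072 to 70602014, plus strand) and Slc17a7 (ENSMUSG00000070570.5, chromosome 7, 45163949 to 45176142, plus strand). Of 21 measured GABAergic and fast-spiking markers, 18 were higher in F cells (85.7%, interval 63.7 to 96.95%), and the number was 18 within the older and 16 within the newer batch. For GABAergic and fast-spiking markers the median log2 fold was 2.21, at percentile 100 of the random lists, and the share was 100% on the log2 scale. Gad2 was higher in F cells, with a log2 fold of 2.10. Cox6a2 was lower in F cells, with a log2 fold of -1.18. Of 22 measured glutamatergic markers, 0 were higher in F cells (0%, interval 0 to 15.4%), and the number was 3 within the older and 2 within the newer batch. For glutamatergic markers the median log2 fold was -3.64, at percentile 0.05 of the random lists. Camk2a was lower in F cells, with a log2 fold of -1.53. Cox6a2 turned sign without 1 cell, with 0.67 for Cox6a2 without P15. Gad2, Pvalb and Camk2a fell under a 2-fold difference without 1 cell, to 0.93 for Gad2 without F1, 0.083 for Pvalb without F1 and -0.93 for Camk2a without P30. Camk2a fell under a 2-fold difference without the 16 F libraries, to -0.59. Camk2a turned sign with trimmed means, Cox6a2 on the log2 scale, Cox6a2 and Camk2a in the older batch and Gad2 in the newer batch.

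Sst, the neuropeptide somatostatin, marks another interneuron class and was found in 7 of 25 F cells and 5 of 59 P cells, and Vip, also a neuropeptide of interneurons, was found in 4 of 25 F cells and 4 of 59 P cells. Fezf2, a transcription factor of deep-layer projection neurons, had counts in P cells and none in F cells. Of 12 measured markers of other interneuron classes, 10 were higher in F cells (83.3%, interval 51.6 to 97.9%), and the number was 1 within the older and 10 within the newer batch. For markers of other interneuron classes the median log2 fold was 3.07, at percentile 100 of the random lists, and the share was 41.7% with trimmed means and 9.09% in the older batch. Markers of other interneurons higher in F cells had log2 folds of 3.41 for Nos1, 5.86 for Calb1, 5.24 for Sst and 0.43 for Vip. Cck was lower in F cells, with a log2 fold of -2.68. Lamp5 had 1 count over the F cells, and its pooled ratio of F to P was 0.000527 (interval 1.33e-05 to 0.00294). Of 12 measured upper-layer pyramidal markers, 3 were higher in F cells (25%, interval 5.49 to 57.2%), and the number was 3 within the older and 3 within the newer batch. For upper-layer pyramidal markers the median log2 fold was -0.87, at percentile 46.8 of the random lists, and the share was 66.7% with trimmed means. Pou3f1 was higher in F cells, with a log2 fold of 3.80. Mdga1 had 3 counts over the F cells, and its pooled ratio of F to P was 0.0983 (interval 0.02003 to 0.293). Of 18 measured deep-layer pyramidal markers, 1 was higher in F cells (5.56%, interval 0.141 to 27.3%), and the number was 6 within the older and 2 within the newer batch. For deep-layer pyramidal markers the median log2 fold was -1.65, at percentile 20.8 of the random lists, and the share was 37.5% in the older batch. Tle4 was higher in F cells, with a log2 fold of 1.85. Pcp4 was lower in F cells, with a log2 fold of -6.95. Fezf2 had 0 counts in F cells and 25912 in 23 P cells, at least 1831-fold lower in F cells by pooled counts. Its log2 fold by mean CPM was -6.79. Pou3f1 and Tle4 turned sign without 1 cell, with -1.99 for Pou3f1 without F20 and -5.46 for Tle4 without F24. Mdga1 fell under a 2-fold difference without 1 cell, to -0.62 without P56. Pou3f1 turned sign with pooled counts, Tle4 with trimmed means, Tle4 on the log2 scale, Sst and Mdga1 in the older batch, Nos1, Pou3f1 and Tle4 without the 16 F libraries and Pou3f1 without libraries under 100000 counts. Bounds for genes at 0 are ratios of pooled counts with a floor of 3 counts over the group, and do not bound the fold of mean CPM. By the same 3, 0 cells allow a count in up to 12% of F cells or 5.08% of P cells, which does not limit the cells that express the gene.

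Cell by cell, 16 of 25 F cells had more GABAergic than glutamatergic markers at 10 CPM or more (64%, interval 42.5 to 82.03%). The reverse held for 50 of 59 P cells (84.7%, interval 73.01 to 92.8%). The 6 P cells with more GABAergic markers were P15, P3, P31, P57, P67 and P75. The 6 F cells with more glutamatergic markers were F13, F17, F18, F20, F26 and F8, and all but F8 were among 16 F libraries that share reads, described with the leading genes. In libraries under 100000 counts, such as F20 (94372) and F26 (81302), 1 count is over 10 CPM and passes as a marker. Deeper libraries need more counts to reach that level. F cells had a median of 4 GABAergic and 2 glutamatergic markers, and P cells had 1 and 6. Libraries F11 and F12, each with 7 GABAergic markers and 1 glutamatergic marker, may hold RNA of 1 cell. They count as 2 cells here and in every share of F cells.

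**Figure D1:**
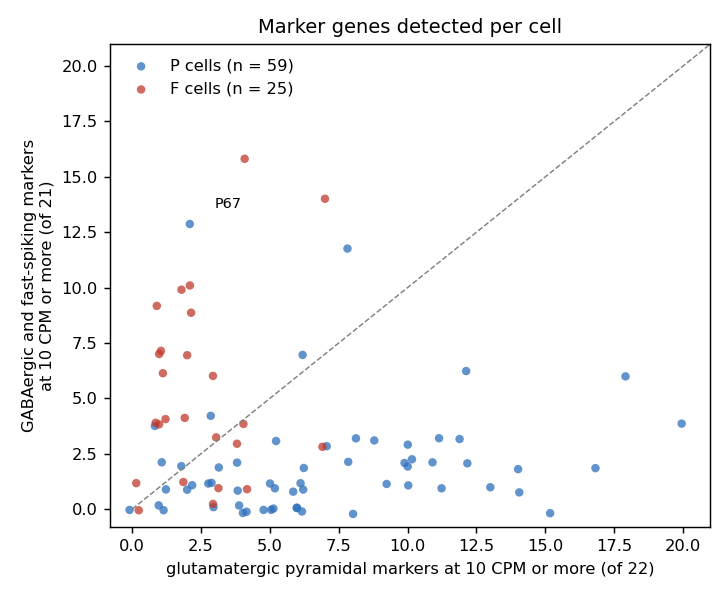
Each point is 1 library, with the number of the 22 glutamatergic markers at 10 CPM or more on the x axis and of the 21 GABAergic and fast-spiking markers on the y axis, moved slightly to separate overlapping points. Libraries F11 and F12 may hold RNA of 1 cell. In libraries under 100000 counts, 1 count is over 10 CPM. Red points are the 25 F cells and blue points the 59 P cells, the dashed line marks equal numbers, and the P cell with the most GABAergic markers, P67, has 13 of them and 2 glutamatergic markers.

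The leading genes were ranked in each direction by the share of the 1475 pairs of an F and a P cell in which 1 group had the higher CPM. Baiap2, a postsynaptic scaffold protein, led those higher in P cells, with 7.03 CPM in F cells and 333 CPM in P cells. It was found in 12% (95% interval 2.55 to 31.2%) against 77.97% (65.3 to 87.7%) of cells, and the P cell was higher in 85.02% of pairs. Sv2b, a synaptic vesicle protein, had 4 counts over the F cells and 44834 over the P cells. Leading genes lower in F cells had log2 folds of -5.38 for Baiap2, -4.83 for R3hdm1, -7.11 for Arpp21, -8.73 for Miat, -4.64 for Rnf112, -3.52 for Camk2b, -3.45 for Ttyh1, -7.18 for Sv2b, -6.04 for Chst1, -4.67 for Rasgef1a, -3.15 for Ahi1 and -2.27 for Celf2. Camk2b is a calmodulin-dependent kinase, Celf2 an RNA-binding protein and Miat a long noncoding RNA. Without 16 F libraries that share reads, described below, log2 folds were -3.40 for R3hdm1, -2.11 for Camk2b, -2.01 for Ttyh1 and -1.69 for Ahi1. They were -3.44 for Rnf112, -5.33 for Chst1 and -3.29 for Rasgef1a. They were -8.02 for Baiap2, -7.31 for Arpp21, -8.70 for Miat, -7.08 for Sv2b and -2.32 for Celf2. R3hdm1 had a count in 1 of the 16 and 8 of the other 9 F libraries, but Arpp21 in 9 and 6. None of these 12 changed sign under the alternatives tried, but several of these could not turn them. The naming rule required the same direction in both batches, so those 2 settings could not. Changing the low-count filter leaves the fold as it was, and a pseudocount cannot turn its sign. The 12 were also picked from these data by share of pairs and a fold of at least 2, which makes a turn less likely.

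Klhl18 led the genes higher in F cells, found in 88% (95% interval 68.8 to 97.5%) against 18.6% (9.69 to 30.9%) of cells, with the F cell higher in 88.1% of pairs. Fndc5, the precursor of irisin, was found in 25 of 25 F cells and 54 of 59 P cells, and Celsr1, an adhesion receptor of the cadherin superfamily, in 22 of 25 F cells and 18 of 59 P cells. The leading genes higher in F cells had log2 folds of 3.93 for Klhl18, 6.86 for Celsr1, 1.15 for Pno1, 3.002 for Pnpla6, 3.79 for Dnahc7b, 3.12 for Fndc5, 6.05 for Polrmt, 1.49 for Tug1, 3.43 for Pi4ka, 1.56 for Hsd17b11 and 3.50 for Gad1. Some of these values rest on a block of libraries. In the 16 F libraries numbered 13 to 28, all of the newer batch, a set of 27 genes was found together, and most of them kept similar ratios to each other. These libraries were picked by at least 2 counts of each of Klhl18, Celsr1 and Pno1, so the loss of fold of these 3 without them, and the turn of Celsr1, follows from the pick. The genes of the set were picked as rare outside them, which partly fixes the same loss for Pnpla6, Kcnmb1 and Grid2ip. Pnpla6, Dnahc7b, Fndc5, Pi4ka and Hsd17b11 also had a count in all 16. Without these libraries, an alternative chosen after the data were seen, the log2 folds were 0.33 for Pnpla6, -2.08 for Dnahc7b, 2.11 for Fndc5 and 3.76 for Polrmt. They were 1.27 for Tug1, 2.28 for Pi4ka, -3.51 for Hsd17b11 and 4.29 for Gad1. Pno1 fell under a 2-fold difference without 1 cell, to 0.32 without F20. Pnpla6 and Dnahc7b turned sign with pooled counts, Celsr1, Dnahc7b and Hsd17b11 without the 16 F libraries and Pno1 without libraries under 100000 counts. For Polrmt, 1 cell held 85.6% of the F sum, and 1 cell held over 50% of the sum of the higher group for 77 of the 141 genes reported by the naming rule. The share of pairs pointed against the mean for 12 of them, Cox6a2, Tle4, Slc4a4, C1qb, Tyrobp, Gabrb2, Chrnb2, Oprl1, P2ry1, P2rx4, Slc6a15 and Gfap.

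**Figure D2:**
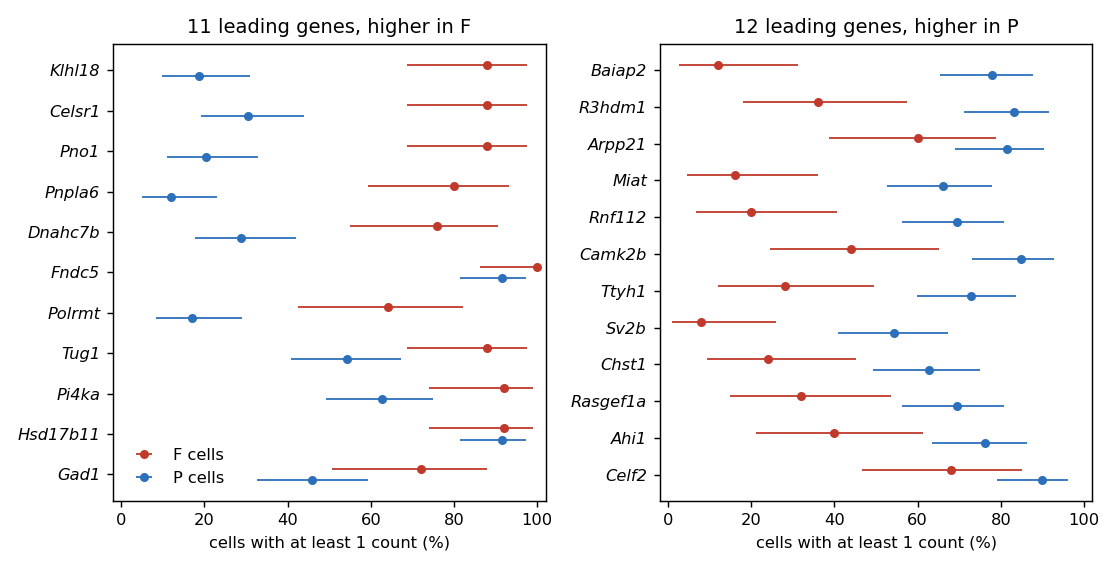
The x axis gives the percent of cells with at least 1 count of each leading gene, red for the 25 F cells and blue for the 59 P cells, with exact binomial 95% intervals. The left panel holds 11 genes higher in F cells, of which Celsr1, Dnahc7b and Hsd17b11 turned sign without the 16 F libraries (for Celsr1 this follows from how they were picked), Pnpla6 and Dnahc7b with pooled counts and Pno1 without libraries under 100000 counts, and the right panel the 12 higher in P cells, from Baiap2, in 12% of F and 77.97% of P cells, to Celf2.

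**Figure D3:**
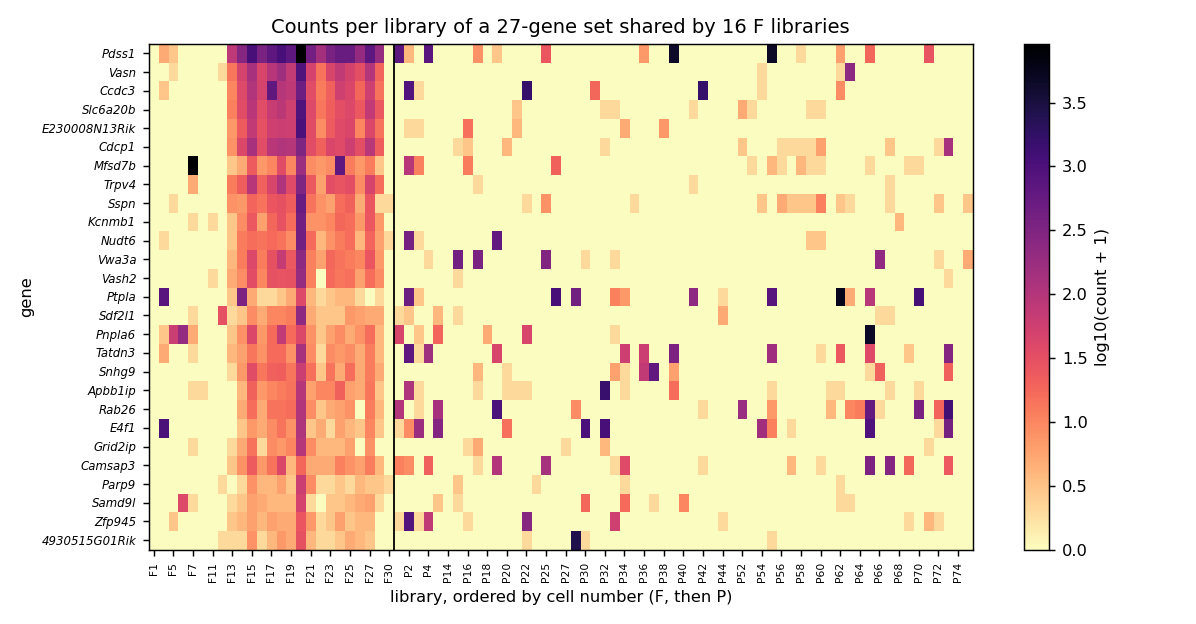
Counts on a log10(count + 1) color scale for the 27 genes of the shared set on the y axis and the 84 libraries on the x axis, F then P by cell number, with a line between the groups. The 16 libraries F13 to F28 carry 23 or more of the 27 genes each, and no other library carries more than 12, which the choice of libraries and genes partly fixes.

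Markers of glia and vessels, which a pipette can draw in with a neuron, were present in both groups. Slc1a2, the astrocytic glutamate transporter, averaged 612 CPM in F and 3114 CPM in P cells, and Mbp, a myelin protein, 159 and 748 CPM. Gfap, an astrocyte filament protein, was found in 5 of 25 F cells and 9 of 59 P cells, and Cx3cr1, the fractalkine receptor of microglia, in 9 of 25 F cells and 31 of 59 P cells. Of 15 measured astrocyte markers, 4 were higher in F cells (26.7%, interval 7.79 to 55.1%), and the number was 4 within the older and 4 within the newer batch. For astrocyte markers the median log2 fold was -2.04, at percentile 15.4 of the random lists. Astrocyte markers higher in F cells had log2 folds of 2.3999 for Clu and 2.72 for Slc4a4. Astrocyte markers lower in F cells had log2 folds of -3.00 for Aldoc, -2.34 for Slc1a2 and -2.34 for Gfap. Of 12 measured oligodendrocyte markers, 4 were higher in F cells (33.3%, interval 9.92 to 65.1%), and the number was 0 within the older and 4 within the newer batch. For oligodendrocyte markers the median log2 fold was -2.60, at percentile 6.5 of the random lists. Their share was 0% with a minimum of 21 cells (2 members) and 0% in the older batch. Oligodendrocyte markers higher in F cells had log2 folds of 5.07 for Mobp and 7.09 for Pdgfra. Mbp was lower in F cells, with a log2 fold of -2.23. Of 14 measured microglia markers, 6 were higher in F cells (42.9%, interval 17.7 to 71.1%), and the number was 0 within the older and 6 within the newer batch. For microglia markers the median log2 fold was -1.59, at percentile 21.3 of the random lists. Their share was 7.14% with pooled counts, 0% with trimmed means and 7.14% on the log2 scale. It was 71.4% with a minimum of 21 cells (7 members), 0% in the older batch and 0% without the 16 F libraries. Microglia markers higher in F cells had log2 folds of 1.44 for C1qb and 3.86 for Tyrobp. Microglia markers lower in F cells had log2 folds of -4.71 for Cx3cr1 and -3.86 for Ctss. Of 7 measured endothelial and mural markers, 1 was higher in F cells (14.3%, interval 0.361 to 57.9%), and the number was 3 within the older and 1 within the newer batch. For endothelial and mural markers the median log2 fold was -0.63, at percentile 47.9 of the random lists. Their share was 0% with a minimum of 21 cells (1 member) and 60% in the older batch. Vwf was higher in F cells, with a log2 fold of 6.77. Cspg4 was lower in F cells, with a log2 fold of -5.48. Pdgfrb had 3 counts over the F cells, and its pooled ratio of F to P was 0.007397 (interval 0.00152 to 0.0216). Gfap, C1qb, Tyrobp, Pdgfrb and Cspg4 turned sign without 1 cell, with 0.62 for Gfap without P16, -1.39 for C1qb without F18, -3.29 for Tyrobp without F18, 0.10 for Pdgfrb without P16 and 0.19 for Cspg4 without P41. Pdgfra fell under a 2-fold difference without 1 cell, to 0.62 without F23. Pdgfra and Vwf fell under a 2-fold difference without the 16 F libraries, to 0.0015 for Pdgfra and 0.0033 for Vwf. C1qb turned sign with pooled counts, Slc4a4, C1qb and Tyrobp with trimmed means, Gfap, C1qb and Tyrobp on the log2 scale, C1qb with TMMwsp factors, Gfap, C1qb and Tyrobp in the older batch and C1qb and Tyrobp without the 16 F libraries.

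Among genes that most neurons express, Uchl1, a ubiquitin hydrolase, was higher in F cells, and Rbfox3, which encodes the NeuN antigen, lower. Fos, an activity-induced transcription factor, averaged 1722 CPM in F and 139.9 CPM in P cells. It was found in 12 of 25 F cells and 33 of 59 P cells, and the F cell was higher in only 52.3% of pairs. Of 20 measured pan-neuronal genes, 13 were higher in F cells (65%, interval 40.8 to 84.6%), and the number was 14 within the older and 11 within the newer batch. For pan-neuronal genes the median log2 fold was 0.58, at percentile 99.2 of the random lists, and the share was 30% with trimmed means and 40% on the log2 scale. Uchl1 was higher in F cells, with a log2 fold of 2.78. Pan-neuronal genes lower in F cells had log2 folds of -4.20 for Elavl4 and -5.25 for Rbfox3. Of 23 measured immediate early and stress genes, 9 were higher in F cells (39.1%, interval 19.7 to 61.5%), and the number was 9 within the older and 8 within the newer batch. For immediate early and stress genes the median log2 fold was -1.24, at percentile 41.5 of the random lists. Early and stress genes higher in F cells had log2 folds of 3.97 for Hspa1a and 3.61 for Fos. Nr4a1 was lower in F cells, with a log2 fold of -4.45. Arc had 3 counts over the F cells, and its pooled ratio of F to P was 0.001197 (interval 0.000247 to 0.00350). Of 84 measured nuclear genes of oxidative phosphorylation, 41 were higher in F cells (48.8%, interval 37.7 to 59.96%), and the number was 63 within the older and 38 within the newer batch. For nuclear genes of oxidative phosphorylation the median log2 fold was -0.11, at percentile 99.6 of the random lists, and the share was 28.6% with trimmed means, 36.9% on the log2 scale, 75% in the older batch, 54.8% without the 16 F libraries, 51.2% without P67 and 51.3% without members caught by name. Ndufaf1, Ndufaf2, Ndufaf3, Ndufaf4, Ndufaf5 and Ndufaf7 are in this list by name only, and without them the number was 40 of 78. Respiratory chain genes higher in F cells had log2 folds of 3.92 for Ndufa12 and 2.98 for Ndufs8. Respiratory chain genes lower in F cells had log2 folds of -1.18 for Cox4i1 and -2.96 for Atp5k. Ndufa12 turned sign without 1 cell, with -0.073 for Ndufa12 without F27. Cox4i1 fell under a 2-fold difference without 1 cell, to -0.89 without P37. Hspa1a fell under a 2-fold difference without the 16 F libraries, to 0.072. Nr4a1, Cox4i1 and Atp5k turned sign in the older batch.

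Among ion channels, Kcnc2, a Kv3 potassium channel of fast-spiking cells, averaged 903 CPM in F and 36.8 CPM in P cells, and was found in 12 of 25 F cells and 21 of 59 P cells. Kcnd2, a Kv4 potassium channel, averaged 3.91 and 213 CPM, and was found in 6 of 25 F cells and 26 of 59 P cells. Of 35 measured voltage-gated potassium channels, 17 were higher in F cells (48.6%, interval 31.4 to 66.01%), and the number was 11 within the older and 16 within the newer batch. For voltage-gated potassium channels the median log2 fold was -0.060, at percentile 95.04 of the random lists, and the share was 28.6% with trimmed means, 52.6% with a minimum of 21 cells and 51.4% without P67. Kcnq1ot1 is in this list by name only, and without it the number was 16 of 34. Kcnc2 was higher in F cells, with a log2 fold of 4.58. Kv channels lower in F cells had log2 folds of -3.74 for Kcnf1 and -5.44 for Kcnd2. Kcnv2 had 2 counts over the P cells, and its pooled ratio of F to P was 16.5 (interval 3.14 to 163). Of 24 measured other potassium channels, 6 were higher in F cells (25%, interval 9.77 to 46.7%), and the number was 6 within the older and 7 within the newer batch. For other potassium channels the median log2 fold was -1.18, at percentile 24.4 of the random lists. Other potassium channels higher in F cells had log2 folds of 4.23 for Kcnj12 and 3.11 for Kcnmb2. Other potassium channels lower in F cells had log2 folds of -3.04 for Kcnn2, -1.94 for Kcnma1 and -1.86 for Kcnj4. Kcnmb1 had 3 counts over the P cells, and its pooled ratio of F to P was 983 (interval 335 to 4778). Kcnj4 fell under a 2-fold difference without 1 cell, to -0.33 without P20. Kcnmb1 fell under a 2-fold difference without the 16 F libraries, to 0.0095. Kcnmb2 turned sign in the older batch, Kcnv2 without the 16 F libraries. Kcnmb1, a subunit of BK channels, belongs to the shared set, and 16 of its 18 F cells were among the 16 libraries. F20 held 432 of its 625 F counts.

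Cacna2d2, an auxiliary calcium channel subunit, was higher in F cells, and Cacna2d1 of the same family lower, at 1.99 against 249 CPM. Of 12 measured sodium and HCN channels, 4 were higher in F cells (33.3%, interval 9.92 to 65.1%), and the number was 7 within the older and 3 within the newer batch. For sodium and HCN channels the median log2 fold was -0.87, at percentile 69.8 of the random lists, and the share was 75% with pooled counts, 58.3% in the older batch and 58.3% without the 16 F libraries. Hcn2 was higher in F cells, with a log2 fold of 2.15. Sodium and HCN channels lower in F cells had log2 folds of -4.51 for Scn3a and -1.20 for Scn2b. Scn7a had 3 counts over the F cells, and its pooled ratio of F to P was 0.00315 (interval 0.000649 to 0.009204). Of 19 measured calcium channel subunits, 5 were higher in F cells (26.3%, interval 9.15 to 51.2%), and the number was 3 within the older and 4 within the newer batch. For calcium channel subunits the median log2 fold was -1.17, at percentile 28.4 of the random lists. Calcium channel subunits higher in F cells had log2 folds of 5.07 for Cacna2d2 and 1.503 for Cacnb1. Calcium channel subunits lower in F cells had log2 folds of -6.39 for Cacna2d1, -2.01 for Cacna1a and -1.13 for Cacnb4. Scn2b and Cacnb4 fell under a 2-fold difference without 1 cell, to -0.23 for Scn2b without P40 and -0.75 for Cacnb4 without P55. Cacna2d2 and Cacna1a fell under a 2-fold difference without the 16 F libraries, to 0.85 for Cacna2d2 and -0.93 for Cacna1a. Scn2b and Cacnb1 turned sign with pooled counts, Scn2b, Cacnb1 and Cacna1a in the older batch and Hcn2, Scn2b, Cacnb1 and Cacnb4 without the 16 F libraries. Hcn2 had a count in 16 and Cacnb1 in 9 of the 16 libraries with the shared set.

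Receptors for amino acid transmitters went both ways. Grin2b, an NMDA receptor subunit, averaged 84.2 CPM in F and 784 CPM in P cells, and was found in 7 of 25 F cells and 43 of 59 P cells. It was found in 1 of the 16 F libraries with the shared set and in 6 of the other 9. Its log2 fold without the 16 was -1.74. Gabra5, a GABA-A receptor subunit, averaged 3.07 and 96.8 CPM. Of 19 measured ionotropic glutamate receptor genes, 9 were higher in F cells (47.4%, interval 24.4 to 71.1%), and the number was 9 within the older and 9 within the newer batch. For ionotropic glutamate receptor genes the median log2 fold was -0.29, at percentile 77.5 of the random lists, and the share was 57.9% with pooled counts. Grid2ip and Grina are in this list by name only, and without them the number was 7 of 17. Ionotropic glutamate receptor genes higher in F cells had log2 folds of 5.81 for Grid2ip, 3.06 for Grik1 and 3.33 for Grin3a. Grin2b was lower in F cells, with a log2 fold of -3.20. Grik4 had 0 counts in F cells and 5148 in 10 P cells, at least 364-fold lower in F cells by pooled counts. Grin2a had 0 counts in F cells and 820 in 9 P cells, at least 57.9-fold lower in F cells by pooled counts. Of 7 measured metabotropic glutamate receptors, 2 were higher in F cells (28.6%, interval 3.67 to 70.96%), and the number was 0 within the older and 3 within the newer batch. For metabotropic glutamate receptors the median log2 fold was -0.91, at percentile 55.4 of the random lists, and the share was 0% with trimmed means and 0% in the older batch. Grm2 had 1 count over the F cells, and its pooled ratio of F to P was 0.00685 (interval 0.000173 to 0.0383). Grm8 had 0 counts in F cells and 23803 in 16 P cells, at least 1682-fold lower in F cells by pooled counts. Grm4 had 0 counts in F cells and 4940 in 8 P cells, at least 349-fold lower in F cells by pooled counts. Of 14 measured GABA receptor subunits, 3 were higher in F cells (21.4%, interval 4.66 to 50.8%), and the number was 5 within the older and 2 within the newer batch. For GABA receptor subunits the median log2 fold was -1.23, at percentile 44.1 of the random lists. Gabrb2 was higher in F cells, with a log2 fold of 2.09. GABA receptor subunits lower in F cells had log2 folds of -5.84 for Gabrb1, -4.59 for Gabra5 and -5.14 for Gabra4. Of 11 measured glycine and acetylcholine receptor subunits, 4 were higher in F cells (36.4%, interval 10.9 to 69.2%), and the number was 5 within the older and 4 within the newer batch. For glycine and acetylcholine receptor subunits the median log2 fold was -1.20, at percentile 5.55 of the random lists. Their share was 0% with a minimum of 21 cells (2 members) and 55.6% in the older batch. Glycine and acetylcholine receptors higher in F cells had log2 folds of 2.11 for Chrnb1 and 1.92 for Chrnb2. Glycine and acetylcholine receptors lower in F cells had log2 folds of -1.97 for Glrb, -1.86 for Chrm1 and -5.13 for Glra2. Grin2a, Grm4, Grm2, Chrnb1 and Chrnb2 fell under a 2-fold difference without 1 cell, to -0.55 for Grin2a without P42, -0.26 for Grm4 without P55, -0.81 for Grm2 without P17, 0.92 for Chrnb1 without F20 and 0.27 for Chrnb2 without F1. Glrb and Chrm1 fell under a 2-fold difference without the 16 F libraries, to -0.78 for Glrb and -0.65 for Chrm1. Grin2b turned sign with pooled counts, Gabrb2 with trimmed means, Gabrb2 on the log2 scale, Grin2b, Glrb and Glra2 in the older batch and Grid2ip without the 16 F libraries. Grid2ip belongs to the shared set, and 14 of its 15 F cells were among the 16 libraries.

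Adora1, the A1 adenosine receptor, was lower in F cells, at 4.02 against 830.3 CPM, and was found in 6 of 25 F cells and 34 of 59 P cells. Cckbr, a cholecystokinin receptor, was also lower, found in 1 of 25 F cells and 21 of 59 P cells. Of 11 measured monoamine receptors, 4 were higher in F cells (36.4%, interval 10.9 to 69.2%), and the number was 2 within the older and 4 within the newer batch. For monoamine receptors the median log2 fold was -0.78, at percentile 46.5 of the random lists. Their share was 54.5% on the log2 scale and 0% with a minimum of 21 cells (2 members). Htr7 was higher in F cells, with a log2 fold of 3.71. Hrh3 was lower in F cells, with a log2 fold of -4.53. Hrh2 had 0 counts in P cells and 16 in 10 F cells, at least 25.2-fold higher in F cells by pooled counts. Hrh1 had 0 counts in F cells and 5104 in 9 P cells, at least 361-fold lower in F cells by pooled counts. Of 15 measured neuropeptide, opioid and cannabinoid receptors, 5 were higher in F cells (33.3%, interval 11.8 to 61.6%), and the number was 2 within the older and 6 within the newer batch. For neuropeptide, opioid and cannabinoid receptors the median log2 fold was -1.10, at percentile 17.8 of the random lists, and the share was 6.67% with trimmed means. Neuropeptide and related receptors higher in F cells had log2 folds of 3.06 for Adcyap1r1 and 2.43 for Oprl1. Cckbr was lower in F cells, with a log2 fold of -7.26. Npy1r had 1 count over the F cells, and its pooled ratio of F to P was 0.000246 (interval 6.23e-06 to 0.00137). Vipr1 had 0 counts in F cells and 3272 in 14 P cells, at least 231-fold lower in F cells by pooled counts. Of 6 measured purinergic and adenosine receptors, 4 were higher in F cells (66.7%, interval 22.3 to 95.7%), and the number was 1 within the older and 3 within the newer batch. For purinergic and adenosine receptors the median log2 fold was 0.13, at percentile 76.02 of the random lists. Their share was 33.3% with pooled counts, 0% with trimmed means and 38.9% with no low-count filter. It was 0% with a minimum of 21 cells (1 member), 40% after thinning, 33.3% in the older batch and 16.7% without the 16 F libraries. P2rx4 was higher in F cells, with a log2 fold of 4.02. Purinergic receptors lower in F cells had log2 folds of -7.37 for Adora1 and -5.90 for P2ry12. P2ry1 had 2 counts over the F cells, and its pooled ratio of F to P was 0.786 (interval 0.0855 to 3.53), against a log2 fold of 1.10 by mean CPM. Of 20 measured plasma membrane transporters, 8 were higher in F cells (40%, interval 19.1 to 63.9%), and the number was 8 within the older and 8 within the newer batch. For plasma membrane transporters the median log2 fold was -0.55, at percentile 63.1 of the random lists. Transporters higher in F cells had log2 folds of 5.20 for Slc1a6 and 2.44 for Slc6a15. Slc6a7 was lower in F cells, with a log2 fold of -5.36. P2rx4 turned sign without 1 cell, with -0.69 for P2rx4 without F1. P2ry1, Slc1a6 and Slc6a15 fell under a 2-fold difference without 1 cell, to 0.17 for P2ry1 without F28, 0.97 for Slc1a6 without F6 and 1.00 for Slc6a15 without F15. Hrh2 fell under a 2-fold difference without the 16 F libraries, to 0.057. P2ry1 turned sign with pooled counts, Hrh3 with trimmed means, Adcyap1r1 in the older batch, P2rx4 in the newer batch, P2ry1 after thinning and P2ry1 without the 16 F libraries. Of the 10 F cells with Hrh2, a histamine receptor, 9 were among the 16 libraries.

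Among axon guidance genes, Epha4, an ephrin receptor, averaged 1.47 CPM in F and 202 CPM in P cells, and was found in 6 of 25 F cells and 32 of 59 P cells. Nrp2, a semaphorin coreceptor, averaged 0.604 and 95.9 CPM. Cdh11, a cadherin, was found in 6 of 25 F cells and 31 of 59 P cells, and Tyro3, a receptor kinase, in 4 of 25 F cells and 30 of 59 P cells. Of 55 measured axon guidance receptors and ligands, 9 were higher in F cells (16.4%, interval 7.77 to 28.8%), and the number was 20 within the older and 8 within the newer batch. For axon guidance receptors and ligands the median log2 fold was -1.80, at percentile 2.12 of the random lists, and the share was 30.9% with pooled counts, 41.7% in the older batch and 29.1% without the 16 F libraries. Unc50 is in this list by name only, and without it the number was 8 of 54. Guidance genes higher in F cells had log2 folds of 2.13 for Dcc, 3.36 for Sema4g and 3.50 for Sema3a. Guidance genes lower in F cells had log2 folds of -6.36 for Epha4, -5.92 for Nrp2 and -1.21 for Plxna2. Of 26 measured cadherins and protocadherins, 7 were higher in F cells (26.9%, interval 11.6 to 47.8%), and the number was 9 within the older and 6 within the newer batch. For cadherins and protocadherins the median log2 fold was -1.13, at percentile 17.1 of the random lists, and the share was 11.5% with trimmed means. Cadherins higher in F cells had log2 folds of 2.98 for Cdh9, 1.32 for Pcdh11x and 4.16 for Cdh4. Cadherins lower in F cells had log2 folds of -5.80 for Cdh11, -1.67 for Pcdh17 and -3.55 for Pcdh7. Of 53 measured synaptic adhesion molecules, 18 were higher in F cells (33.96%, interval 21.5 to 48.3%), and the number was 23 within the older and 17 within the newer batch. For synaptic adhesion molecules the median log2 fold was -0.82, at percentile 48.3 of the random lists, and the share was 20.8% with trimmed means. Synaptic adhesion molecules higher in F cells had log2 folds of 2.84 for Nxph3, 1.90 for Nxph1 and 1.39 for Lrfn1. Synaptic adhesion molecules lower in F cells had log2 folds of -3.27 for Ptprf, -1.55 for Cadm2 and -2.02 for Ptprd. Of 19 measured receptor tyrosine kinases, 8 were higher in F cells (42.1%, interval 20.3 to 66.5%), and the number was 6 within the older and 8 within the newer batch. For receptor tyrosine kinases the median log2 fold was -0.32, at percentile 68.4 of the random lists, and the share was 57.9% on the log2 scale. Receptor kinases higher in F cells had log2 folds of 1.17 for Musk, 3.51 for Egfr and 4.54 for Alk. Tyro3 was lower in F cells, with a log2 fold of -6.99. Kit had 0 counts in F cells and 11491 in 8 P cells, at least 812-fold lower in F cells by pooled counts. Pcdh11x and Nxph1 turned sign without 1 cell, with -0.68 for Pcdh11x without F5 and -1.42 for Nxph1 without F24. Plxna2, Lrfn1, Musk and Alk fell under a 2-fold difference without 1 cell, to -0.98 for Plxna2 without P70, 0.67 for Lrfn1 without F28, 0.55 for Musk without F28 and 0.30 for Alk without F2. Cadm2 fell under a 2-fold difference without the 16 F libraries, to -0.12. Cdh4 turned sign with trimmed means, Dcc, Plxna2, Cdh9, Pcdh11x, Cdh4, Pcdh7, Nxph3, Musk and Egfr in the older batch and Plxna2, Cdh9, Nxph3, Nxph1, Lrfn1, Musk and Egfr without the 16 F libraries. Beside the guidance genes, all measured genes stood at 34.7% higher in F cells as reported, 34.7% with pooled counts, 33.4% without the 16 F libraries and 35.4% in the older batch. Nxph3 had counts in F cells only in the 16 libraries with the shared set, and Musk had counts in 11 of them.

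**Figure D4:**
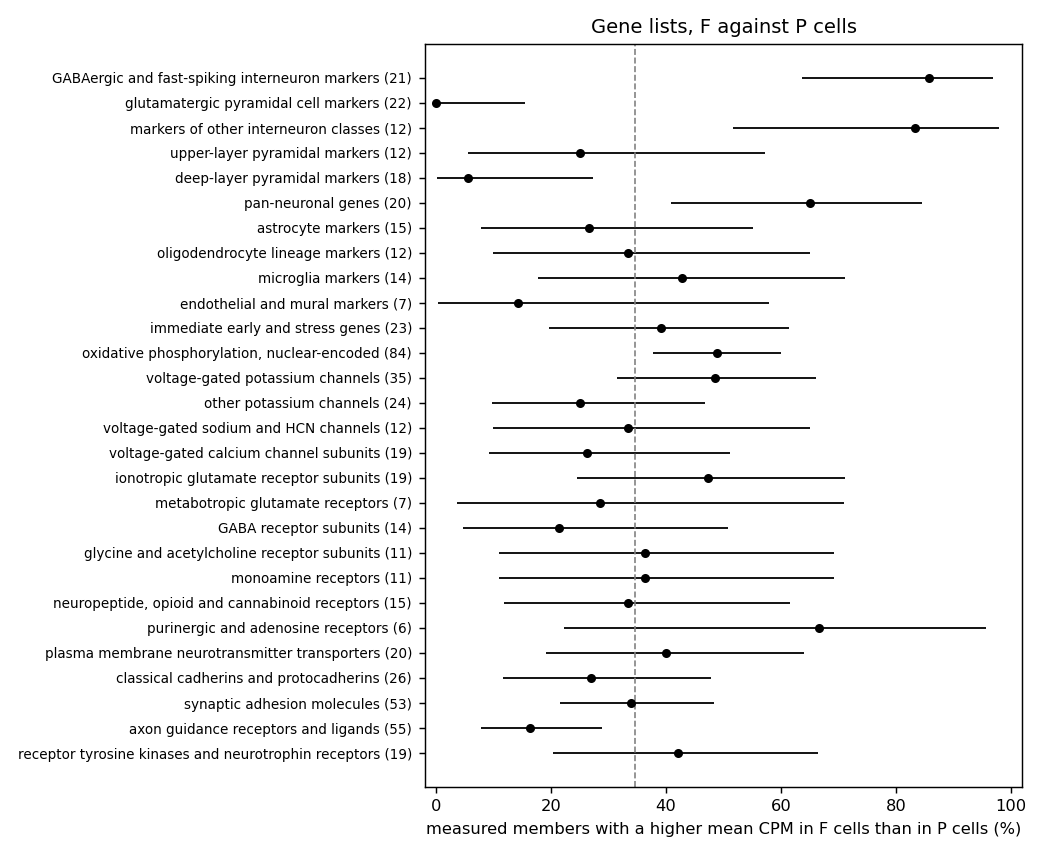
For each of the 28 gene lists, the percent of measured members (their number in parentheses) with a higher mean CPM in F than in P cells, with its exact binomial 95% interval over members, which are not independent. The dashed line is the 34.7% of all 11324 measured genes, with the GABAergic list above it and the glutamatergic list below it, and the list of other interneuron classes above it except in the older batch (1 of 11 members with a count there).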

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

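The tests that leave out the 16 libraries, average F11 and F12, drop Rn45s from the totals, or leave out shallow libraries, P67 or list members caught by name only were chosen after the data were seen. No paired analysis was possible because no test was made and the cell numbers only name cells. The GABAergic share stayed between 76.2 and 100% and the glutamatergic share between 0 and 14.3% under all alternatives tried. Over all list shares and depth values, 423 stayed within the interval or spread, 35 moved and 2 were counted as reversed. Both were for other interneuron classes, where most members were no longer higher in F cells. This count did not use the share of all measured genes. With trimmed means the list stood at 41.7%, still above the 18.7% of all measured genes under that setting. Only in the older batch did it fall below them, at 9.09% against 35.4%. Of the gene folds, 1350 moved by under 1.5 times, 731 by more, and 77 turned sign. The 1350 include 141 without the low-count filter and 91 with a minimum of 21 cells, settings that leave every gene's fold as it was. A pseudocount of 10 cannot turn a sign, so its 28 list shares, counted among the 423, could only stay the same. Detection shares stayed within their intervals 290 times and left them 274 times. With thinned counts alone, 143 stayed and 139 left. The median log2 fold of all measured genes, -0.79 as reported, was 0 with trimmed means, -0.15 on the log2 scale, -0.32 with a pseudocount of 10, -0.085 without the low-count filter, -0.90 with a minimum of 21 cells, -0.57 in the older and -1.01 in the newer batch. Trimming puts genes found in few cells at 0 in both groups, which counts as not higher in F. A gene at 0 in both groups gave no fold, and shares in a subset leave out members with no count in it. Percentages are shares of members higher in F cells. For the values that follow, the cause was not tested.

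Pooled counts gave 7.14% for microglia markers, 75% for voltage-gated sodium and HCN channels and 30.9% for axon guidance receptors and ligands. Pooled counts also turned log2 folds, to -0.93 for Pnpla6, -0.032 for Dnahc7b, -0.029 for Pou3f1, -1.15 for C1qb, 0.40 for Scn2b, -1.37 for Cacnb1, 0.52 for Grin2b and -0.016 for P2ry1. Trimmed means gave 41.7% for markers of other interneuron classes, 66.7% for upper-layer pyramidal markers, 30% for pan-neuronal genes, 0% for microglia markers, 28.6% for oxidative phosphorylation, nuclear-encoded, 28.6% for voltage-gated potassium channels, 0% for metabotropic glutamate receptors, 6.67% for neuropeptide, opioid and cannabinoid receptors, 0% for purinergic and adenosine receptors, 11.5% for classical cadherins and protocadherins and 20.8% for synaptic adhesion molecules. Trimmed means also turned log2 folds, to -0.46 for Tle4, -0.065 for Slc4a4, -0.097 for C1qb, -0.18 for Tyrobp, -2.34 for Gabrb2, 0.034 for Hrh3, -0.0090 for Cdh4 and 0.10 for Camk2a. Differences of mean log2 values gave 100% for GABAergic and fast-spiking interneuron markers, 40% for pan-neuronal genes, 7.14% for microglia markers and 36.9% for oxidative phosphorylation, nuclear-encoded. Differences of mean log2 values also turned log2 folds, to 0.027 for Cox6a2, -0.59 for Tle4, -0.036 for C1qb, -0.16 for Tyrobp, -0.13 for Gabrb2 and 0.014 for Gfap. TMMwsp factors turned the log2 folds to -2.37 for C1qb. A minimum of 21 cells left few members in these lists. It gave 0% for oligodendrocyte lineage markers (2 members), 71.4% for microglia markers (7) and 0% for endothelial and mural markers (1). It also gave 0% for glycine and acetylcholine receptor subunits (2), monoamine receptors (2) and purinergic and adenosine receptors (1). Thinned counts turned the log2 folds to -0.28 for P2ry1. The older batch alone gave 9.09% for markers of other interneuron classes, 37.5% for deep-layer pyramidal markers, 0% for oligodendrocyte lineage markers, 0% for microglia markers, 60% for endothelial and mural markers, 75% for oxidative phosphorylation, nuclear-encoded, 0% for metabotropic glutamate receptors, 41.7% for axon guidance receptors and ligands, 4978 for median genes detected in F and 5857 for median genes detected in P. The older batch alone also turned log2 folds, to 6.497 for Cox6a2, 0.20 for Mdga1, -7.51 for C1qb, -5.06 for Tyrobp, 0.45 for Nr4a1, 1.12 for Cox4i1, 1.41 for Atp5k, -0.059 for Kcnmb2, 3.81 for Scn2b, -0.96 for Cacnb1, 0.032 for Cacna1a, 0.94 for Grin2b, 0.41 for Glrb, 1.59 for Glra2, -0.022 for Adcyap1r1, -6.67 for Cdh9, -1.52 for Pcdh11x, -0.19 for Cdh4, 3.17 for Pcdh7, -0.80 for Nxph3, -0.33 for Dcc, 0.42 for Plxna2, -0.14 for Musk, -0.044 for Egfr, 0.42 for Camk2a, -3.63 for Sst and 0.060 for Gfap. The newer batch alone turned the log2 folds to -0.75 for P2rx4 and -0.12 for Gad2. Leaving out the 16 F libraries with shared reads gave 0% for microglia markers, 16.7% for purinergic and adenosine receptors and 29.1% for axon guidance receptors and ligands. Leaving out the 16 F libraries with shared reads also turned log2 folds, to -1.92 for Celsr1, -2.08 for Dnahc7b, -3.51 for Hsd17b11, -0.77 for Nos1, -2.18 for Pou3f1, -4.33 for Tle4, -3.07 for C1qb, -2.26 for Tyrobp, -0.0013 for Kcnv2, -1.76 for Hcn2, 0.13 for Scn2b, -0.99 for Cacnb1, 0.34 for Cacnb4, -0.048 for Grid2ip, -0.082 for P2ry1, -3.69 for Cdh9, -3.81 for Nxph3, -0.11 for Nxph1, -0.0093 for Lrfn1, 0.25 for Plxna2, -1.06 for Musk and -0.024 for Egfr. Leaving out libraries under 100000 counts turned the log2 folds to -0.27 for Pno1 and -2.02 for Pou3f1. The 16 libraries were picked by counts of Klhl18, Celsr1 and Pno1, so the turn of Celsr1 without them follows from the pick.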

Other observations

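All tests in this part were chosen after the results they bear on had been seen.

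The 16 libraries F13 to F28 were picked by at least 2 counts of each of Klhl18, Celsr1 and Pno1, and the 27 genes, such as Pdss1, Vasn and Ccdc3, by a count in at least 14 of the 16 and in under 25% of the other libraries. The median SD over the 16 libraries of the log2 share of a gene in the set total was 0.826, against 2.166 for 76 ordinary genes, which is consistent with reads of 1 shared source, whose origin was not tested, though Ptpla at 2.15 and Mfsd7b at 1.47 varied more. The next 2 tests leave out the 3 genes that picked the 16, and replaced earlier forms that the pick of libraries or genes, or 1 gene alone, could set. The pick still sets the outcome of the test of expression common to F cells. For low depth, the genes tested were 20 found in at least 14 of the 16 and rare in the other P libraries. Of all 18 P libraries in the range of totals of the 16, 0 (interval 0 to 18.5%) held at least 50% of them. But the 16 were picked with genes that lead in F over P cells, which made few carriers among P libraries likely beforehand. Low depth therefore stays open. Expression common to F cells stays open, because the other 9 F libraries are those that failed the pick. Splitting F libraries by depth instead cannot decide it. Of the 13 at or above the F median total, 4 carried at least 50% of 25 genes (interval 9.09 to 61.4%). These 25 genes were found in at least 14 of the 16 and in under 25% of P libraries. But the 13 are those same 9 and F14, F16, F24 and F27, which belong to the 16.

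Libraries F11 and F12 had a Pearson r of 0.961 across genes, which are not independent replicates, and the next of 3486 pairs 0.621. Of 36 genes with at least 50 counts in F11 and found in under 10% of the other libraries, 100% were found in F12, which is consistent with RNA of 1 cell in both. Separate cells of 1 type are argued against by the other 388 ordered pairs of F libraries with at least 10 such genes in the first, which shared at most 40% of them. The same library deposited again is argued against by a chi-square of 29.1 per gene over 1282 genes, where sampling noise gives about 1.

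P67 carried 10079 counts of Gad1, 1975 of Gad2, 1335 of Slc32a1, the vesicular GABA transporter, and 8997 of Tac1, a tachykinin precursor, 1 of Arpp21, and 0 of Slc17a7, Camk2a and Baiap2, in a total of 2121153. RNA of a neighbouring interneuron beside that of a glutamatergic cell is argued against by its 61.3 CPM summed over the 22 glutamatergic markers, under the 5th percentile of the other P libraries at 176 CPM, where their median was 4429 CPM, though 1 of the other 58, P27, was lower; this sum replaced a number of markers found to decide nothing. A label swap with an F library stays open, because 0 F libraries had at least the P median of glutamatergic and at most the P median of GABAergic markers, but 6 had more glutamatergic than GABAergic markers. Among these 6, F20 and F26 were so shallow that 1 count passed as a marker. A GABAergic cell recorded as P and a single wrong label cannot be told apart, since its 13 GABAergic markers, where the next P library had 12, are the same under both.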
